A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

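RNA sequencing libraries of the above-ground parts of 4 rice seedling samples were compared, 2 labelled modd mutant (titled modd2) and 2 labelled DongJin wild type. Each sample's group was taken from its own label, and the replicate numbers are those in the sample titles. Each library had 1 gene table. The submitters' processing notes name BWA, Bowtie and RSEM, without versions or roles; the genome build and gene annotation are not given in the sources used here. Per the file headers, each row gives a gene identifier, its transcripts, a length, an expected count and an FPKM value. The expected counts deposited by the authors are RSEM's estimates of reads per gene, in which reads shared by similar genes are split into fractions. The FPKM values deposited by the authors are those counts scaled by effective transcript length and by the reads assigned in the library. Each table lists only genes above 0, so a gene missing from a table was counted as 0 there. The rows fall short of the implied total (below), so a missing row may not be a true 0.

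The totals were 5334814 and 5357608 expected reads in the libraries labelled modd mutant, and 5348748 and 5393972 in the wild type libraries. The listed rows held from 97.8 to 97.9% of the total that the FPKM scale implies. The 100 most abundant genes took 15.5, 16.4, 16.1 and 17.7% of the reads in the same order. In all, 28491 genes were listed in at least 1 library and 23160 in all 4. Libraries of a group were checked for duplicates by a chi-square of their counts, over genes with at least 10 summed reads. The statistic per degree of freedom was 2.54 for the libraries labelled modd mutant and 4.5 for the wild type, above the sampling noise of 1 library counted again, so all 4 were kept as separate samples.

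Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its defaults (a minimum count of 10 scaled to library size and a minimum total of 15), which left 19365. TMM factors were 1.02, 1.01, 1.01 and 0.964. The quasi-likelihood test used robust estimation and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 10.3%. Standard errors of log2 fold changes were computed as the absolute value divided by the square root of the F statistic. FPKM values are given as group means with the SD of 2 libraries. The test was tried on simulated counts for these 19365 genes, with 200 genes changed, in 4 runs. With dispersions on the fitted trend it recovered 75.2% of 2-fold and 99.5% of 4-fold changes, and 3.32% of its calls were false. With each gene's own dispersion it recovered 71.8% and 99%, and 16.6% of its calls were false. In simulations without any changed gene it made 0 to 1 calls with the first kind of dispersion and 9 to 11 with the second.

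Gene lists for ABA signalling, stress, jasmonate, defence, photosynthesis, the clock and markers of other organs were fixed, with locus identifiers, before the data were examined. A further set of lists defined by words in gene descriptions could not be used, because the reference gene table (assembly ASM3414082v1) gives no descriptions and matched 0 of the identifiers in the files. That table was used only to check symbols: 104 of 154 listed symbols were found in it, 102 on the same chromosome as the identifier, and the 2 others (HSP90 and UBQ5) were dropped, which left 152 genes. It gives the symbol OsPYL5 to another gene as well, so loci are printed beside the receptors. Lists with at least 5 tested members, 12 of 21, were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the 12 lists. Of these, 7 passed. With an estimated correlation 0 passed, and with fry 0 passed, in its directional or its mixed form. The preset form of camera takes its degrees of freedom from the number of genes. The estimated form takes them from the libraries, few with 2 libraries per group, so a list needs a far larger statistic to pass. In simulations without changes, camera called 0 of 48 lists with trended dispersions and 3 of 48 with gene-by-gene dispersions. As the simulations were set by dispersions, these counts are no check on camera under correlation between genes. The estimated correlation reached 0.924 in the photosynthesis list.

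Genes are named by a rule fixed beforehand. It takes MODD and OsbZIP46, then the called genes with the largest rises and falls, and then up to 3 members with the smallest adjusted p in each of 10 lists, in order of the set test's p. The second part asked for named genes with a mean of at least 1 FPKM. As no source here pairs identifiers with names, it was limited, as the rule provides, to 2 identifiers that rose and 2 that fell. For groups with 0 reads, folds are lower bounds against a floor of 3 reads over the group, and intervals are at a 95% level.

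Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no count filter, a filter of at least 1 FPKM in 2 libraries, and non-robust estimation. Further ones were limma on log2(FPKM + 1) with and without that filter and on log2(FPKM + 0.1), the replicate number as a block, and leaving out each library in turn. After the data were seen, the receptor list was also tested without OsPYL5. No coordinates are given, since the build behind the files is not stated.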

Results

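Messenger RNA was profiled in the above-ground parts of rice seedlings (Oryza sativa, japonica subspecies) at the 4-leaf stage, grown without a stress treatment. The 2 groups were the DongJin wild type, a Korean japonica cultivar, and a modd mutant from a rice mutant library, with 2 libraries each. MODD is named by the series title as a factor that deactivates and degrades OsbZIP46, a bZIP transcription factor of the abscisic acid (ABA) response, and the comparison asks which transcripts differ between the genotypes in unstressed plants. The gene tables held between 5334814 and 5393972 expected reads per library, and each listed from 25545 to 25735 genes above 0. The labels do not say whether the libraries of a group came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

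MODD (LOC_Os03g11550) was higher in the libraries labelled modd mutant, against its label if the mutation were to lower the transcript. Its level was 36.9 and 46.6 FPKM in the libraries labelled modd mutant and 21.0 and 21.3 FPKM in the wild type libraries, a log2 fold change of 0.93 ± 0.146 (SE, n = 2 per group, edgeR adjusted p = 0.0272). The kind and site of the mutation are not given in the sources used here, and a gene-level count does not show which part of the transcript the reads came from. Directions below are therefore stated for the libraries as labelled. The transcript of OsbZIP46 (LOC_Os06g10880) was at 6.24 ± 1.41 FPKM (SD, n = 2) in the libraries labelled modd mutant and 6.29 ± 2.5 FPKM in the wild type, a log2 fold change of -0.11 ± 0.298 (SE, edgeR adjusted p = 0.885). The sign of that value changed with single libraries left out. OsTPR3, a corepressor of the TOPLESS family, and the histone deacetylase gene HDA702, the 2 partner genes listed, had log2 fold changes of 0.01 and -0.05, with edgeR adjusted p of 0.973 and 0.834.

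In the libraries labelled modd mutant, 2 ABA receptor genes were higher. OsPYL6 (LOC_Os03g18600) was at 195.8 ± 1.74 FPKM against 72.5 ± 17.3 FPKM in the wild type (SD, n = 2 each), 2.63-fold higher. OsPYL5 (LOC_Os05g39580) was at 8.01 ± 0.742 FPKM against 2.28 ± 0.735 FPKM, 3.4-fold higher. Lower transcripts were OsNCED4 (LOC_Os07g05940), coding for a 9-cis-epoxycarotenoid dioxygenase of ABA synthesis, OsTPP1 (LOC_Os02g44230), a trehalose-6-phosphate phosphatase gene, and TIFY10A (LOC_Os03g28940), a jasmonate-responsive JAZ repressor gene. These 5 genes and MODD were the 6 called among the 120 tested genes of the lists fixed before the data were examined.

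**Figure D1:**
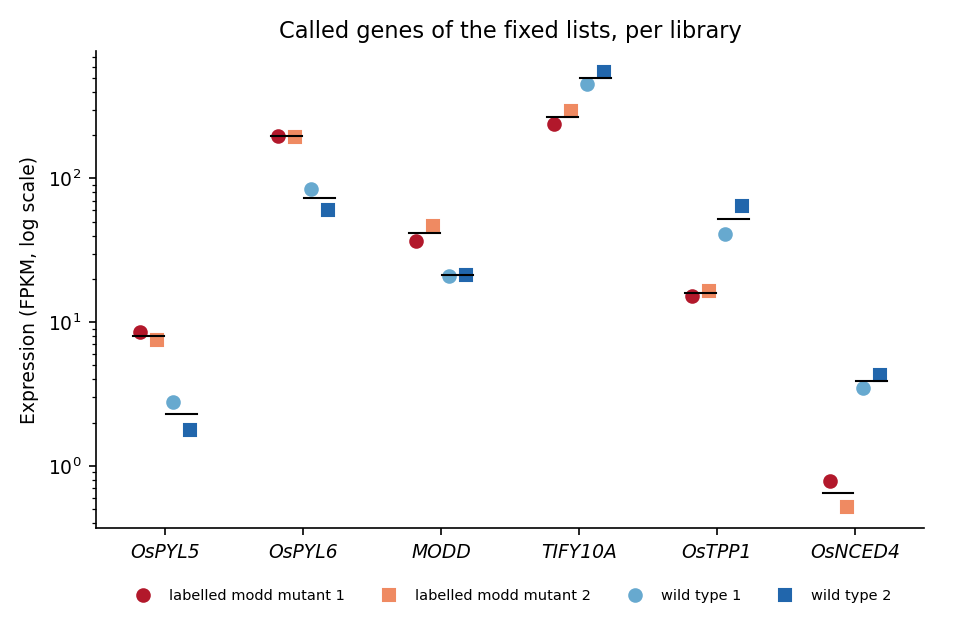
Expression of the 6 called list genes in FPKM on a log axis, with 1 point per library and a bar at the mean of each group of 2 libraries. OsPYL5, OsPYL6 and MODD sit higher in both libraries labelled modd mutant than in both wild type libraries, and TIFY10A, OsTPP1 and OsNCED4 sit lower in both.

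Of the 8 listed ABA receptors, which bind the hormone and then inhibit clade A protein phosphatases, 5 were tested, 2 rose and none fell. The log2 fold change was 1.39 ± 0.138 (SE) for OsPYL6 (edgeR adjusted p = 0.00961) and 1.77 ± 0.274 for OsPYL5 (edgeR adjusted p = 0.0272). OsPYL11 (LOC_Os05g12260) was at 91.7 ± 0.672 against 75.8 ± 3.83 FPKM (SD, n = 2), with a log2 fold change of 0.23 and an edgeR adjusted p of 0.276. OsPYL1 and OsPYL3 had log2 fold changes of -0.04 and -0.16, and their edgeR adjusted p were 0.95 and 0.52. Adjusted over the list alone, the same 2 receptors passed. With an estimated correlation, camera has few degrees of freedom here. A failure there, for this or later lists, need not come from correlation between genes. The list was higher as a set (camera adjusted p = 7.45e-05), but not with an estimated correlation (adjusted p = 0.319) and not on log2(FPKM + 1) values (camera adjusted p = 0.0781). Its mean log2 level relative to all 4 libraries was 0.375 and 0.25 in replicates 1 and 2 labelled modd mutant. In wild type replicates 1 and 2 it was -0.218 and -0.407. The 2 tested root markers described below ranked the libraries in the same order. So did the first principal component of all tested genes, so this order is not particular to root markers. Called members were more frequent than among other tested genes by a two-sided Fisher's exact test (adjusted p = 0.013).

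All 7 tested clade A phosphatase genes (PP2C), whose products are negative regulators of ABA signalling, had log2 fold changes below 0 in the libraries labelled modd mutant, with a median of -0.56. None passed the test over all genes by edgeR, and 3 passed when adjusted over the list alone. OsPP2C30 (LOC_Os03g16170) was at 2.01 ± 0.0849 against 4.57 ± 0.771 FPKM (SD, n = 2), a log2 fold change of -1.23 ± 0.29 (SE, edgeR adjusted p = 0.0831). OsPP2C09 had a log2 fold change of -0.56 (edgeR adjusted p = 0.105) and OsPP2C49 one of -0.58 (edgeR adjusted p = 0.19). As a set the phosphatases were lower with the preset correlation (camera adjusted p = 0.0024) and not with an estimated one (adjusted p = 0.34). Their mean log2 levels were 0.136 and 0.329 in wild type replicates 1 and 2, and -0.181 and -0.284 in the libraries labelled modd mutant.

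Genes of ABA synthesis and breakdown were also lower as a set (camera adjusted p = 0.000344, and adjusted p = 0.319 with an estimated correlation). Their mean log2 levels were 0.213 and 0.532 in wild type replicates 1 and 2, and -0.377 and -0.368 in the libraries labelled modd mutant. Of 8 tested, 1 fell by the test over all genes and 2 adjusted over the list alone. OsNCED4 was at 0.65 ± 0.184 against 3.89 ± 0.587 FPKM (SD, n = 2), 6.08-fold lower, from 9 and 6 reads in the libraries labelled modd mutant and 40 and 50 in the wild type (log2 fold change -2.60 ± 0.354, SE, edgeR adjusted p = 0.0213). OsABA8ox3, which codes for an enzyme that hydroxylates ABA, had a log2 fold change of -0.58 ± 0.175 (SE, edgeR adjusted p = 0.141), and OsNCED1 one of -0.35 ± 0.129 (SE, edgeR adjusted p = 0.218).

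The jasmonate list showed the smallest set p (camera adjusted p = 7.7e-06, lower; adjusted p = 0.319 with an estimated correlation). Of its 10 tested genes, 1 fell over all genes and 6 fell when adjusted over the list alone. TIFY10A was at 267.2 ± 40.1 against 501.2 ± 63.8 FPKM (SD, n = 2), a log2 fold change of -0.95 ± 0.15 (SE, edgeR adjusted p = 0.028). That call did not hold without replicate 1 labelled modd mutant, where the log2 fold change was -0.79 against -0.95. The related JAZ genes TIFY11A (LOC_Os03g08310) and TIFY11D (LOC_Os10g25290) had larger and more variable differences. TIFY11A was at 2.09 ± 1.15 against 18.3 ± 10.1 FPKM (edgeR adjusted p = 0.102), and TIFY11D at 48.5 ± 18.9 against 176 ± 39.7 FPKM (SD, n = 2, edgeR adjusted p = 0.134). The wild type libraries differed within this list too. The mean log2 level of its tested genes, relative to all 4 libraries, was 0.319 and 0.587 in wild type replicates 1 and 2, and -0.603 and -0.303 in the libraries labelled modd mutant.

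None of the 13 tested stress-responsive transcription factor genes passed over all genes by edgeR, and 2 passed adjusted over the list alone, OsNAC3 and OsNAC6. OsNAC6 (LOC_Os01g66120) was at 60.4 ± 17.3 against 160.7 ± 26.3 FPKM (SD, n = 2), a log2 fold change of -1.45 ± 0.237 (SE, edgeR adjusted p = 0.0683). OsNAC3 (LOC_Os07g12340) had a log2 fold change of -1.91 ± 0.36 (SE, edgeR adjusted p = 0.053). With single libraries left out, that fold change ran from -2.57 (without replicate 2 labelled modd mutant) to -1.46 (without replicate 1 labelled modd mutant). OsDREB1C (LOC_Os06g03670), of a family known for cold induction, was at 1.26 ± 0.113 against 20.2 ± 15.5 FPKM (edgeR adjusted p = 0.204), and its wild type libraries stood apart at 9.22 and 31.1 FPKM. OsNAC6 passed with DESeq2 (adjusted p = 0.00495) and non-robust edgeR (0.0306), OsNAC3 with the FPKM filter (0.048) and without a filter (0.00943), and OsDREB1C with non-robust edgeR (0.0411). Over all alternatives their adjusted p ran from 8.49e-07 to 0.414, 8.01e-07 to 0.249 and 1.89e-19 to 0.815. Expected counts of these 3 genes held fractions, so some of their reads were shared with similar genes. The set was lower (camera adjusted p = 0.000172; adjusted p = 0.319 with an estimated correlation). Its mean log2 level relative to all 4 libraries was 0.12 and 0.769 in wild type replicates 1 and 2, and -0.58 and -0.309 in the libraries labelled modd mutant.

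Photosynthesis genes differed little in size but in one direction. All 11 tested members, light-harvesting protein genes (LHCB), PSBS1 and small-subunit genes of Rubisco (RBCS), had log2 fold changes below 0, from -0.42 to -0.09 with a median of -0.25, and none passed by edgeR over all genes or adjusted over the list alone. RBCS at LOC_Os12g19470 was at 374.1 ± 5.38 against 484 ± 73 FPKM (SD, n = 2, edgeR adjusted p = 0.186), with fractional counts that mark reads shared among the copies. LHCB5 and LHCB4 had log2 fold changes of -0.39 and -0.36, with edgeR adjusted p of 0.264 and 0.31. The set was lower (camera adjusted p = 0.000776), not with an estimated correlation (adjusted p = 0.539), and not without wild type replicate 2 (camera adjusted p = 0.116). The mean log2 level of the list was 0.281 in that library, -0.0256 in wild type replicate 1, and -0.213 and -0.0429 in the libraries labelled modd mutant. The 2 tested root markers, LSI1 and OsHKT2;1, had means of -0.479 in wild type replicate 2, -0.0274 in replicate 1, and 0.33 and 0.177 in the libraries labelled modd mutant.

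All 8 tested chlorophyll synthesis genes likewise had log2 fold changes below 0, with a median of -0.31. None passed over all genes by edgeR and 3 passed adjusted over the list alone: OsCHLD, a magnesium chelatase subunit gene (log2 fold change -0.34, edgeR adjusted p = 0.144), and the protochlorophyllide oxidoreductase genes OsPORA (-0.38, edgeR adjusted p = 0.169) and OsPORB (-0.45, edgeR adjusted p = 0.196). As a set they were lower (camera adjusted p = 0.00328; adjusted p = 0.319 with an estimated correlation). Their mean log2 levels were 0.0573 and 0.188 in wild type replicates 1 and 2 and -0.184 and -0.061 in the libraries labelled modd mutant. This order is opposite to that of the root markers, and it is also the order along the first principal component of all tested genes.

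**Figure D2:**
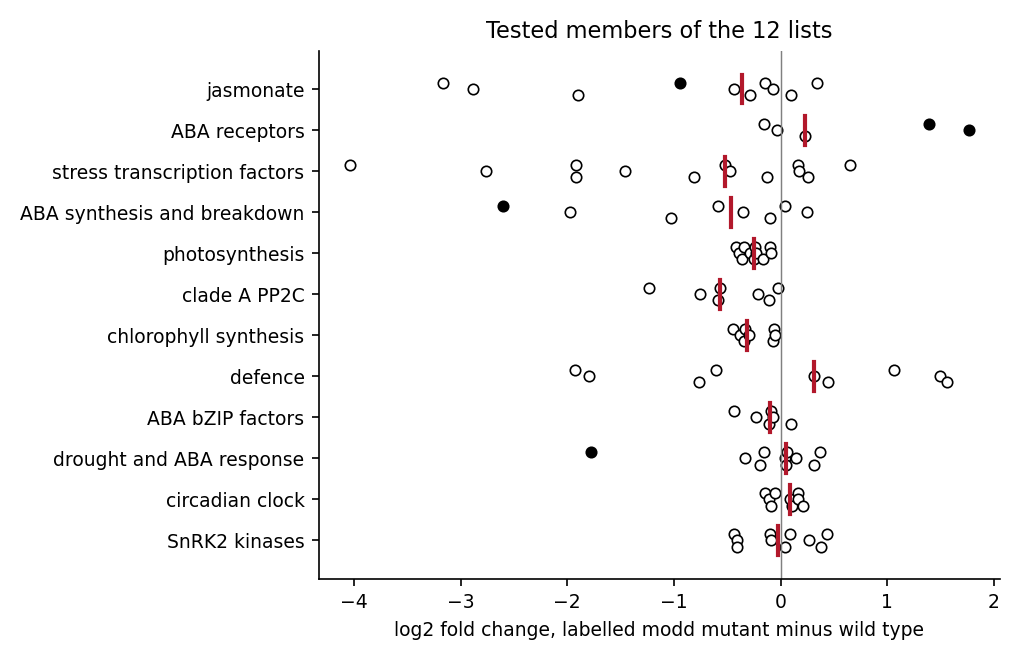
Log2 fold changes (labelled modd mutant minus wild type, x axis) of the tested members of the 12 lists given the set test, in order of the set test's p from the top. Filled points are the genes with an edgeR adjusted p below 0.05, open points the others, and red bars the medians, which run from -0.56 for the clade A PP2C genes to 0.31 for defence.

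The other 5 tested lists did not pass the set test. Of 17 drought and ABA response genes, 10 were tested. Their camera adjusted p was 0.685, with a median log2 fold change of 0.05 and a mean of -0.15. Only OsTPP1 was called, over all genes and adjusted over the list alone, at 15.8 ± 1.01 against 52.4 ± 16.3 FPKM (SD, n = 2, log2 fold change -1.77 ± 0.246, SE, edgeR adjusted p = 0.0455). Its call did not hold when either library labelled modd mutant was left out, with log2 fold changes of -1.70 without replicate 1 (edgeR adjusted p = 0.239) and -1.85 without replicate 2 (0.118), nor without the count filter (-1.78, adjusted p = 0.0602). The dehydrin gene LIP9 had a log2 fold change of 0.31 (edgeR adjusted p = 0.186) and OsASR1 one of 0.37 (edgeR adjusted p = 0.2). Among 6 tested bZIP factors of the ABA pathway, camera's adjusted p was 0.288 and none was called, over all genes or adjusted over the list alone. OsbZIP72 had a log2 fold change of -0.44 (edgeR adjusted p = 0.188), OsbZIP23 one of -0.23 (0.39) and OsbZIP42 one of 0.10 (0.813). SnRK2 kinases and circadian clock genes each had a camera adjusted p of 0.752, and defence genes one of 0.146, with no member of these 3 lists called over all genes. Adjusted over the list alone, 4 of 10 SnRK2 genes passed, 2 higher (SAPK5, SAPK6) and 2 lower (SAPK2, SAPK9), as did 0 of 9 clock genes and 3 of 9 defence genes, all lower. The defence list had a median log2 fold change of 0.31 and a mean of -0.02. Its WRKY members OsWRKY76, OsWRKY45 and OsWRKY71 had values of -1.80, -0.61 and -1.93, with edgeR adjusted p of 0.105, 0.156 and 0.183.

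Markers of other organs were mostly unlisted or not called. Of 6 root markers, LSI2, OsNRT2.1 and OsYSL15 were listed in none of the 4 libraries, and the 2 tested had a median log2 fold change of 0.50 with no call by edgeR over all genes, and OsHKT2;1 higher adjusted over the list alone. The meristem marker OSH1 was under the count minimum, the panicle marker OsMADS14 had a log2 fold change of -0.01, and none of the 3 tested senescence genes was called over all genes. Adjusted over the list alone all 3 passed, OsNAP higher and SGR and NYC1 lower. No heat shock gene on the list reached the count minimum, and the 3 tested diterpenoid phytoalexin genes and the 2 tested housekeeping genes were not called over all genes; adjusted over the list alone the housekeeping gene ACT1 was higher.

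Outside the lists, the largest falls by the naming rule were in LOC_Os04g34670 and LOC_Os01g64320, and the largest rises in LOC_Os08g29580 and LOC_Os06g33200; the files do not pair these identifiers with names. LOC_Os04g34670 was not listed, and so counted as 0 reads, in both libraries labelled modd mutant, and had 33.1 and 35.7 reads in the wild type. If the missing rows are true 0 counts, it was at least 22.8-fold lower against a floor of 3 reads over the group (edgeR adjusted p = 0.0134). LOC_Os01g64320 was not listed in either against 9.9 and 12.7 reads, by the same reading at least 7.5-fold lower (edgeR adjusted p = 0.0467). That call did not hold with upper-quartile factors (adjusted p = 0.0559) or without replicate 1 labelled modd mutant (0.0827), where the fitted log2 fold changes were -6.56 and -6.55 against -6.56. LOC_Os08g29580 had 18 and 23 reads against 2 and 0, a ratio with a 95% counting interval from 5.35 to 176 (edgeR adjusted p = 0.0369). LOC_Os06g33200 had 28 and 37 reads against 7 and 6 (edgeR adjusted p = 0.0367). The wild type counts of LOC_Os04g34670 and LOC_Os01g64320 held fractions, so some of their reads were shared with similar genes. Intervals and floors cover counting error only, and not how shared reads were split.

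Over the 19365 genes tested, 162 were called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 97 higher and 65 lower in the libraries labelled modd mutant. Of these, 75 changed at least 2-fold, 45 higher and 30 lower. Both libraries of one group lay beyond both of the other for all 162, and for 50.3% of all tested genes, where chance gives 33.3%. The first principal component held 60.2% of the variance and placed the libraries labelled modd mutant at -31.4 and -22.3 and the wild type libraries at 9.38 and 44.3. The number of calls varied with the method and was 102 with upper-quartile factors, 350 with DESeq2 (160 higher, 190 lower), 764 without the count filter, and 0 with limma on log2(FPKM + 1), where 3191 genes had an unadjusted p under 0.05. It was 591 without replicate 2 labelled modd mutant, 2483 without wild type replicate 1 and 457 without wild type replicate 2.

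**Figure D3:**
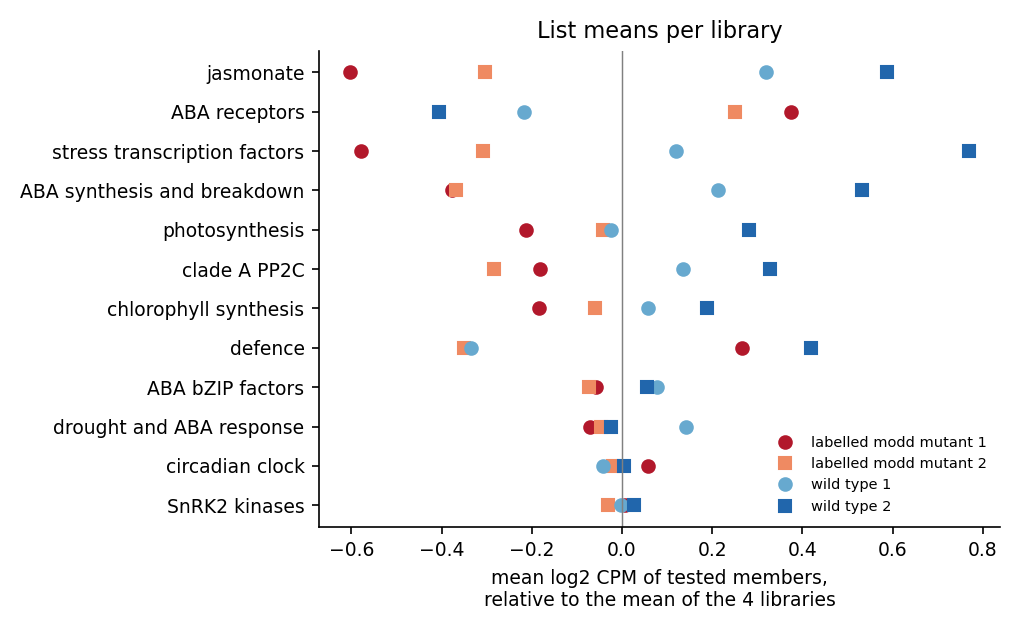
Mean log2 CPM (normalised read counts) of the tested members of each list in each of the 4 libraries (x axis), relative to the mean of the 4. For the stress transcription factors wild type replicate 2 lies at 0.769 and replicate 1 at 0.12, and for the circadian clock genes all 4 libraries lie between -0.0428 and 0.0575.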

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

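All alternatives but the receptor list without OsPYL5 were chosen before the data were examined. The counts of genes changed, higher and lower were 102, 62 and 40 with upper-quartile factors, where fewer than the 162 genes passed and all 102 were among them. They were 350, 160 and 190 with DESeq2 (128 changed at least 2-fold; 134 of the 162 genes kept), and 764, 390 and 374 without the count filter (182 at least 2-fold; 161 kept). limma called 0 genes, and so 0 in either direction and 0 at least 2-fold, on log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered log2(FPKM + 1) values, where 3191, 3127 and 3445 genes had an unadjusted p under 0.05 and the smallest adjusted p were 0.106, 0.116 and 0.215; the cause was not tested. RLE factors called 170 genes and the FPKM filter 213, each with all 162, and non-robust estimation called 180, with 128 of them.

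Leaving out 1 library in turn gave 144 to 2483 genes changed, 76 to 1216 higher, 68 to 1267 lower, and 79 to 762 changed at least 2-fold, with 8 to 36 list genes called. The lowest count of changed genes was without replicate 1 labelled modd mutant, which kept 93 of the 162, and the highest without wild type replicate 1, which kept 161; the single library left in a group is assumed to vary like the other group. With the replicate number as a block, 870 genes were called (377 higher, 493 lower, 292 at least 2-fold, 24 list genes). The deviations of same-numbered libraries correlated at 0.0126 over 2 pairs. With 2 pairs, and labels that tie the number to no batch, pairing is not settled, and the numbers were not used to pair. With the block, 8 lists passed, the defence list among them as lower (camera adjusted p = 2.04e-05), and so did 13 named genes that the unblocked test with TMM and the count filter did not call: TIFY11A, TIFY11D, OsNAC3, OsNAC6, OsDREB1C, OsPP2C30, OsWRKY45, OsWRKY71, OsWRKY76, OsPORA, OsPORB, LHCB4 and LHCB5 (adjusted p from 6.99e-06 to 0.0447).

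DESeq2 called 10 list genes against 6. The log2 fold change of MODD stayed positive in every alternative run, from 0.74 to 1.098 with single libraries left out, and missed the threshold in limma, at 0.94 with and without the filter and 0.97 with the lower pseudocount (adjusted p = 0.113, 0.215 and 0.125). OsbZIP46, not called in any of these, changed sign to 0.0199 on log2(FPKM + 1) values with and without the filter and 0.028 with the lower pseudocount, and ranged from -0.47 to 0.38 with libraries left out. Lists passing fell from 7 to 0 with an estimated correlation (few degrees of freedom) and to 0 with fry (cause not tested). The chlorophyll synthesis estimate was 0.00336, below the preset 0.01. Its unadjusted camera p still went from 0.00191 to 0.0866, which argues for few degrees of freedom over a larger correlation there. For the other passing lists (estimates 0.0242 to 0.924) these causes were not separated. The receptor list still passed without OsPYL5 (camera adjusted p = 0.00429). The defence list passed without replicate 2 labelled modd mutant as higher (adjusted p = 0.0461) and without any 1 of the other 3 libraries as lower. Across the alternatives, the called named genes, MODD included, kept their side of the threshold in 96 cases and missed it in 36, with 0 changes of sign; for genes not called, 300 stayed, 53 passed and 5 changed sign, all 5 of them OsbZIP46. Of these, TIFY11D, OsWRKY76 and OsWRKY71 passed with DESeq2 (adjusted p = 0.00631, 0.0025 and 0.0193) and non-robust edgeR (0.0304, 0.0304 and 0.0356), TIFY11A with the latter (0.0374), and OsPP2C30 and OsPP2C09 without the filter (0.0209 and 0.0467). A gene that an alternative filtered out, or that DESeq2 gave no adjusted p (7509 genes), has no value there. At this depth and with 2 libraries per group, 2-fold changes were recovered in 75.2% of simulated cases.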

Other observations

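The tests of explanations below (shared reads, exchanged labels, flanking loci, transcript lengths, library order, library size, clock genes and other splits) were chosen after the results were seen; the edgeR values and the fits with a library left out were planned. Several defence genes had their highest level in replicate 1 labelled modd mutant. PR1b and PBZ1, which code for pathogenesis-related proteins, were at 34.2 and 37.5 FPKM there and at 6.22 and 12.5 FPKM in replicate 2. They were at 3 and 7.13 FPKM in wild type replicate 1, and at 10.75 and 15.85 FPKM in wild type replicate 2. OsCPS4, a diterpene cyclase gene of momilactone phytoalexin synthesis, was at 8.59 FPKM in the same library and at 1.02, 0.6 and 2.3 FPKM in the others. These genes, picked after their values were seen, were not called by edgeR (adjusted p = 0.604 for PR1b, 0.582 for PBZ1 and 0.639 for OsCPS4).

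A further 4 list genes, also chosen after their values were seen, did not pass the test between genotypes and had wide spreads within them. SNAC1 was at 24.6 and 49.5 FPKM in the libraries labelled modd mutant and at 107.1 and 164.7 FPKM in the wild type (edgeR adjusted p = 0.226). OsABA8ox1, coding for an ABA-hydroxylating enzyme, was at 73 and 131.3 against 275.9 and 506.2 FPKM (edgeR adjusted p = 0.239), and TIFY11B at 14.6 and 22.4 against 87.5 and 176.3 FPKM (edgeR adjusted p = 0.161). OsDREB1B was at 7.37 and 8.69 against 20.1 and 84.9 FPKM (edgeR adjusted p = 0.324). In both genotypes, replicate 2 was above replicate 1 for all 4 genes. The unpaired test counts such a parallel shift as spread, and whether the replicate numbers pair the libraries is not settled.

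MODD was higher in the libraries labelled modd mutant. Its expected counts were fractional in 0 of 4 libraries, which argues against reads shared with similar genes. The next locus by number, LOC_Os03g11560, was also called (log2 fold change 0.94, edgeR adjusted p = 0.0235), and LOC_Os03g11570 and LOC_Os03g11540 had values of 0.56 and 0.58 (edgeR adjusted p = 0.0546 and 0.237); the mean of the 6 flanking loci was 0.32, and 3.92% of 19237 such windows were as high, so an effect of the mutation on its surroundings may contribute, as a hypothesis. An exchange of the group labels would put MODD at -0.929. The libraries labelled wild type held 51.2% of the MODD reads of the others, which goes against an exchange with a line that had lost the transcript (under 10%), while an exchange with a line that keeps part of it stays open, as does an altered transcript; the kind of mutation is not given in the sources used here.

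RSEM's length for MODD, an average over its 2 transcripts, was 1666 in both libraries labelled modd mutant and 1678 in both wild type libraries. Among 3896 genes with at least 2 transcripts and at least 100 reads in each library, 2 had lengths equal within each genotype and different between them. The other was LOC_Os08g09210, and the other 2 ways to split the libraries gave 2 and 4 such genes. The genotype split thus had no excess of such genes, but the pattern was rare for any given gene. MODD was named before the data were examined and the length check was chosen afterwards. These counts therefore do not decide whether the MODD transcript was altered.

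The genes called between genotypes also ordered the libraries within them. Of the 162, 139 (85.8%) had wild type replicate 2 farther from the libraries labelled modd mutant than replicate 1, against 63.8% of all 19365 tested genes, and 130 (80.2%) had replicate 1 labelled modd mutant farther out, against 55.8%; these shares are raised by choosing genes with the same libraries, since 1 deviant library would give them too. Among the 457 genes called without wild type replicate 2, 450 of them in the set of 19365, that library was then farther out than its group mate in 72.9% of the 450, and among the 144 called without replicate 1 labelled modd mutant, that library was farther in 59%, near the share of all genes (the same shares were 3.62% for wild type replicate 1 and 5.51% for replicate 2 labelled modd mutant); a plant or sample state that varied within the genotypes may have this effect, but a single deviant wild type library or a batch that follows the replicate numbers cannot be told apart from it with 2 libraries per group. The share over all genes took its directions from every library, so it is no exact baseline for shares from fits without the library placed. Library totals differed by a factor of 1.01, which argues against library size. The 9 tested clock genes differed by at most 0.227 (log2) between the wild type libraries and 0.259 between those labelled modd mutant, which argues against harvests several hours apart. An effect of genotype on the same genes stays open, and more plants per genotype, harvested in mixed order, would test it.

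The genotype split called 162 genes, and the highest of the other splits of the 4 libraries into 2 and 2 called 0. Each of those other splits puts 1 library of each genotype in each group. A genotype difference then widens the spread within their groups and hinders calls, so the 0 is no measure of chance. Of the 3 splits, 1 (the real one) gave as many, and 3 splits are too few for a share under 0.05.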
